A study of Mus musculus with 11 samples.

How the data were processed

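The samples were hippocampi of C57BL/6 mice, either lacking importin α5 (KO) or wild type (WT), collected 30 min after an intraperitoneal injection of vehicle or of FG7142 at 5 mg/kg. RNA with an integrity number of at least 7 was made into libraries with the TruSeq RNA v2 kit. According to the submitters' processing notes, the programs CASAVA 1.8.2, TopHat2 2.0.10, HTSeq 0.6.1p1 and DESeq 1.18.0 and the genome build mm10 were used, with no role or order given for each. The authors deposited a table of raw counts, which holds 1 read count per gene symbol and library for 23420 genes and 11 libraries. The deposited normalized table gives a signal in which each count was divided by 1 size factor per library, and it was used only to check that relation. Library totals ran from 57568942 to 79657647 counted reads, and 18208 to 18637 genes had at least 1 read in a library. Counting error is therefore small for most genes, and the spread between animals, an edgeR common dispersion of 0.024, sets the precision.

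Libraries were grouped by genotype and treatment from their descriptions, into 3 vehicle-treated WT, 3 vehicle-treated KO, 3 FG7142-treated WT and 2 FG7142-treated KO libraries. One library was taken as 1 animal, as the descriptions put it. No pair of libraries of a group agreed within sampling noise, with chi-square per degree of freedom from 20.8 to 99.3 within groups. Replicate numbers were not taken to pair libraries, since nothing in the descriptions links them.

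Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 16553 genes. Library sizes were scaled by TMM, 1 model with a term per group was fitted to all 11 libraries with robust quasi-likelihood, and each contrast was tested by the quasi-likelihood F test. The 7 contrasts were KO against WT under vehicle, under FG7142 and averaged over treatments, FG7142 against vehicle in WT, in KO and averaged over genotypes, and the interaction. P values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. If no gene changed, a share of 0.05 would on average have an unadjusted p under 0.05. The share found was 4.68% for KO against WT under vehicle, 13.8% under FG7142 and 12.5% averaged over treatments. For FG7142 against vehicle it was 3.32% in WT, 11.5% in KO and 8.83% averaged over genotypes, and it was 6.0% in the interaction. Levels are given in CPM, read counts scaled by the library total times its TMM factor.

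The comparisons, the tests, the gene lists and the rule for naming genes were set before the data were examined. Kpna1, Sphk1 and Mecp2 were named in every comparison, and Fos, Arc, Npas4, Egr1, Nr4a1, Junb, Fosb, Egr2, Dusp1 and Btg2 in those with a drug effect. Genes past the threshold with a mean log2 CPM of at least 1 and no overlap between arms were named up to 12 per direction. Where fewer than 5 genes passed, the 5 with the smallest p were named. Up to 4 members with the smallest p were named from each list that passed its test, leaving some out for length in the order of p.

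Of 35 fixed lists, 34 had a tested member. They cover immediate early genes, delayed activity-regulated genes, the glucocorticoid response, heat shock, nuclear transport receptors, sphingolipid metabolism, DNA methylation, MeCP2-responsive genes, GABA, glutamate and peptide or monoamine signalling, interferon-stimulated genes, ribosomal proteins, the respiratory chain, clock output, sex-linked transcripts and genes near Kpna1. Marker lists covered dentate, CA1, CA3 and CA2 neurons, interneurons, astrocytes, oligodendrocytes and their precursors, microglia, vessels, choroid plexus, meninges, ependyma, thalamus, neocortex, striatum and blood. The 35th list, of mitochondrially encoded transcripts, had 0 members in the table. Each list was tested with camera from limma 3.58.1 with its preset correlation of 0.01, adjusted over the 34 lists of a comparison. Camera with an estimated correlation and fry were alternatives. A list's score in a library is the mean over members of log2 CPM relative to the mean of the 11 libraries.

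Gene positions came from GENCODE vM21 and RefSeq annotations of the mouse build that mm10 names. Of the 23420 symbols, 21737 were found in GENCODE, 211 in RefSeq and 1295 through a RefSeq synonym, while 137 were found nowhere and 40 were ambiguous.

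Alternatives were RLE and upper quartile scaling, no filter, a filter of 50 reads in 2 libraries, DESeq2 1.42.0, limma-voom, a block by replicate number, fits of the compared groups alone and leaving out each library. Alternatives chosen after seeing the data were the choroid plexus score, the meningeal score or both as covariates, the astrocyte score as a covariate, and leaving out the 4 libraries with Ttr at or above 9 log2 CPM. The tests were checked on simulated data of the same depth, group sizes and dispersion. Each simulation changed 200 genes with a mean log2 CPM of at least 1 by 1.5-, 2- or 4-fold, and 1 list by 1.25-fold. Genes varied independently of each other in it. In the simulation of KO against WT under vehicle edgeR made 8 false calls among 162, and DESeq2 50 among 235, and under FG7142 they made 4 among 152 and 36 among 206. The edgeR test recovered 52.2% of 1.5-fold, 83.6% of 2-fold and 93.9% of 4-fold changes under vehicle. With so many genes changed at once the adjusted threshold is easier to pass than where few genes change. These shares can therefore overstate the power in the real data. Plots and checks used Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. No column with values per library was left unused.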

Results

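RNA was sequenced from the hippocampus of mice lacking importin α5 (KO) and of wild-type mice (WT), 30 min after an intraperitoneal injection of vehicle or of 5 mg/kg FG7142, an anxiogenic partial inverse agonist at the benzodiazepine site of GABA receptors. Importin α5, encoded by Kpna1, is an adaptor that binds proteins carrying a nuclear localization signal and takes them into the nucleus. The 11 libraries fell into 4 groups, with 3 libraries of vehicle-treated WT mice, 3 of vehicle-treated KO mice, 3 of FG7142-treated WT mice and 2 of FG7142-treated KO mice. The series' design text states that 1 animal of the last group had been removed as an outlier. Each library was described as coming from a mouse of its group, and no 2 libraries of the same group agreed within sampling noise (10 pairs). Of 23420 genes 16553 were tested. Log2 fold changes are given with ± their standard error.

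Kpna1 separated the genotypes in all 11 libraries. Its level was 149 ± 6.17 CPM (read counts scaled by library total; SD, n = 3) in WT and 2.05 ± 0.0503 CPM (SD, n = 3) in KO animals given vehicle. After FG7142 it was 138 ± 18 CPM (SD, n = 3) in WT and 2.01 ± 0.0709 CPM (SD, n = 2) in KO. The KO level was 1.37% of WT under vehicle and 1.46% under FG7142, from 118 to 153 reads per KO library against 8188 to 10477 per WT library. The gene lies on chromosome 16 of mm10, from 35978750 to 36037131 on the plus strand, and which part is deleted was not given in the sources used here. Over both treatments Kpna1 was lower in KO by a log2 fold change of -6.14 ± 0.092 (adjusted p = 1.5e-11, edgeR). FG7142 left Kpna1 within its spread, at -0.12 ± 0.087 in WT and -0.031 ± 0.13 in KO.

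**Figure D1:**
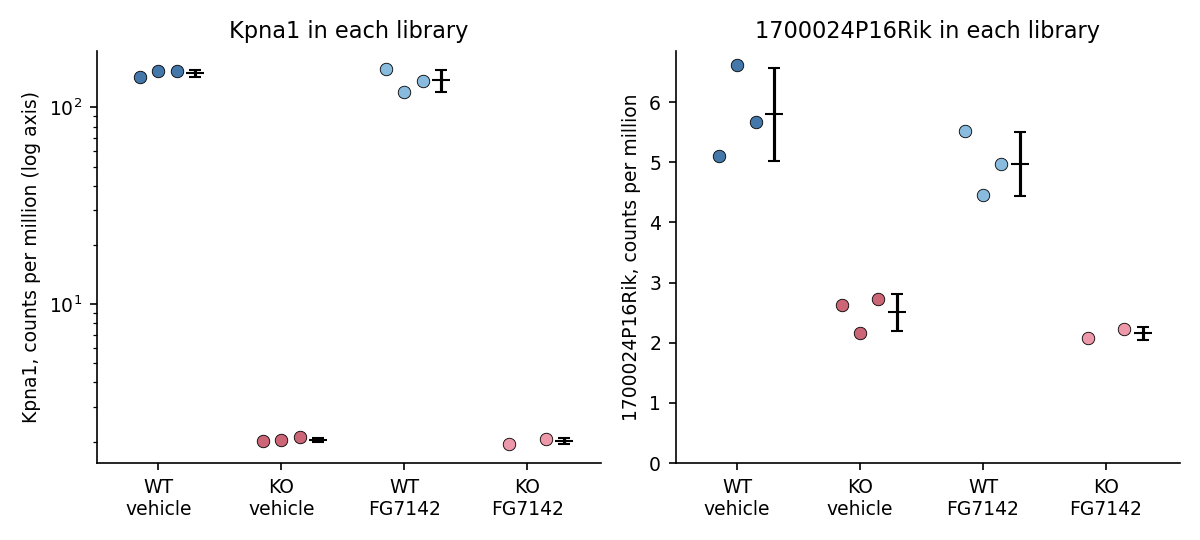
CPM of Kpna1 (left, log axis) and 1700024P16Rik (right, linear axis) in each of the 11 libraries by group; points are libraries and the bar beside them is the mean ± SD (n = 3, 3, 3 and 2). Kpna1 lay at 120 to 156 CPM in the WT libraries and at 1.96 to 2.11 CPM in the KO libraries, and 1700024P16Rik at 4.45 to 6.62 CPM in WT and 2.08 to 2.72 CPM in KO.

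Markers of tissue next to the hippocampus differed between libraries of a group. Ttr, the thyroid hormone carrier made by the choroid plexus, ran from 12.5 to 3992 CPM, with 4 libraries at or above 9 on the log2 CPM scale. Those were 1 vehicle-treated WT library, 2 vehicle-treated KO libraries and 1 FG7142-treated KO library, and no FG7142-treated WT library was among them. The score of 29 meningeal and fibroblast markers was 0.533 ± 0.083 (SD, n = 3) in KO under vehicle, -0.281 ± 0.676 (SD, n = 3) in WT under vehicle, 0.039 ± 0.474 (SD, n = 3) in WT after FG7142 and -0.438 ± 0.187 (SD, n = 2) in KO after FG7142. These differences were left in place in the comparisons that follow.

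**Figure D2:**
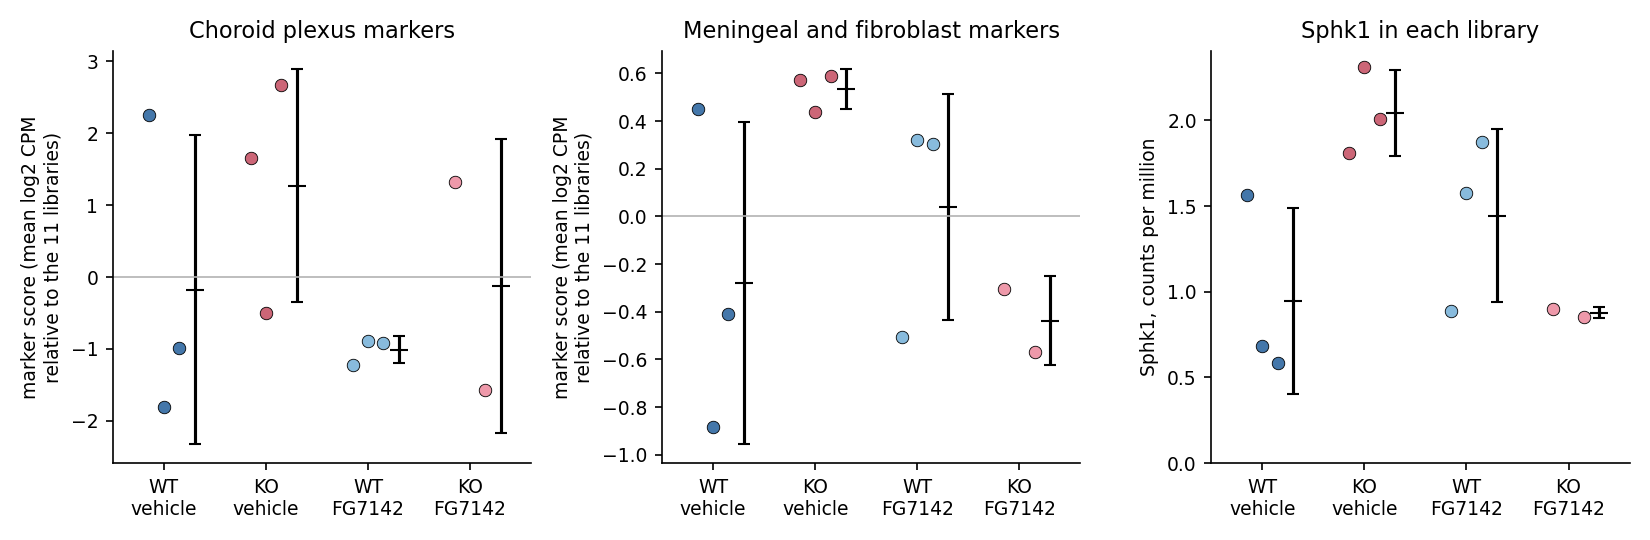
Marker scores of the choroid plexus list (left) and of the meningeal and fibroblast list (middle), as mean log2 CPM relative to the mean of the 11 libraries, and Sphk1 in CPM (right), in each library by group; points are libraries and the bar beside them is the mean ± SD (n = 3, 3, 3 and 2). The 6 libraries with a meningeal score above 0 had 107 to 152 reads of Sphk1 and the other 5 had 40 to 59.

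The first comparison asked what loss of importin α5 did to hippocampal transcripts without drug. Kpna1 was the 1 gene past the threshold of 16553 tested (-6.18 ± 0.11, adjusted p = 1.4e-10). Next by p came 1700024P16Rik, a protein-coding gene listed by RefSeq as Fyb2, at -1.21 ± 0.15 (adjusted p = 0.0590, 3 of 3 KO libraries below the 3 WT libraries). Acta1 (0.81 ± 0.12) and Atp2a1 (2.70 ± 0.46), which encode skeletal muscle actin and a calcium pump of muscle, and Gjb2 (0.92 ± 0.15), a gap junction gene of the meninges, were higher in KO without passing (adjusted p = 0.244, 0.364 and 0.248). Sphk1, which makes sphingosine-1-phosphate, was at 2.04 ± 0.253 CPM in KO and 0.945 ± 0.542 CPM in WT (SD, n = 3 each), a log2 fold change of 1.11 ± 0.37 (adjusted p = 0.987, edgeR; 1.69 without WT vehicle replicate 1). The methyl-CpG binding protein gene Mecp2 differed by -0.10 ± 0.079 (adjusted p = 0.987).

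Of 34 gene lists fixed before the data were examined, 9 passed camera's test with its preset correlation in KO against WT under vehicle, 5 toward higher and 4 toward lower values, and none of the 9 did with an estimated correlation (lowest adjusted p = 0.547). Meningeal and fibroblast markers were higher in KO (28 of 29 members above 0, median 0.74, adjusted p = 1.6e-20, and adjusted p = 0.547 with an estimated correlation). Aldh1a2 was at 1.03 ± 0.33 and Bgn at 0.54 ± 0.15. Choroid plexus markers went the same way (29 of 29 members above 0, median 0.86, adjusted p = 3.0e-06, and adjusted p = 0.697 with an estimated correlation). Calml4 was at 0.94 ± 0.81. Cytosolic ribosomal protein genes were slightly higher (76 of 77 members above 0, median 0.14, adjusted p = 1.9e-17, and adjusted p = 0.547 with an estimated correlation), Rps10 at 0.36 ± 0.12. Short transcripts tended to be higher in this comparison, and random lists matched for transcript length had a median of 0.043. Myelin and oligodendrocyte markers were lower (22 of 24 members below 0, median -0.38, adjusted p = 3.8e-09, and adjusted p = 0.547 with an estimated correlation), among them Sox10 at -0.31 ± 0.087 and Ermn at -0.44 ± 0.16. Oligodendrocyte precursor markers lay lower as well (12 of 14 members below 0, median -0.14, adjusted p = 6.2e-04, and adjusted p = 0.547 with an estimated correlation). Vcan was at -0.28 ± 0.11. Delayed activity-regulated genes were higher (18 of 25 members above 0, median 0.17, adjusted p = 0.020, and adjusted p = 0.547 with an estimated correlation). The neurosecretory gene Vgf was at 0.56 ± 0.15 and Nptx2 at 0.71 ± 0.28. Interneuron markers (18 of 25 members below 0, median -0.12, adjusted p = 0.011, and adjusted p = 0.547 with an estimated correlation) and genes of GABAergic signalling (22 of 27 members below 0, median -0.083, adjusted p = 0.018, and adjusted p = 0.547 with an estimated correlation) were lower, with Cnr1 at -0.28 ± 0.079, Htr3a at -0.37 ± 0.12 and the GABA transporter gene Slc6a1 at -0.16 ± 0.078. Interferon-stimulated genes were higher (22 of 29 members above 0, median 0.17, adjusted p = 0.038, and adjusted p = 0.697 with an estimated correlation). Bst2 was at 0.71 ± 0.25. Adjusted over the list alone, Gjb2 was higher as 1 of the meningeal markers, against 0 over all genes tested. In edgeR 775 genes had an unadjusted p under 0.05. At 4.68% of genes tested, this was below the share of 0.05 that unchanged genes would give. The number was 458 without WT vehicle replicate 2, 425 without KO vehicle replicate 3 and 1414 without KO vehicle replicate 1. DESeq2 called 9 genes and limma-voom 1. Whichever single library was left out, 4 of the 9 lists (meningeal, ribosomal, oligodendrocyte and precursor) passed in the same direction. The choroid plexus median was -0.0012 without KO vehicle replicate 3, 3.19 without WT vehicle replicate 1 and 0.34, not passing, without WT vehicle replicate 2. Of the vehicle-treated libraries, GABAergic genes did not pass without WT replicate 1 or KO replicate 1 or 3, interneuron markers without WT or KO replicate 1, delayed activity-regulated genes without WT replicate 1 or KO replicate 3, and interferon-stimulated genes without WT or KO replicate 2 or 3. Medians of lists that still passed were 0.47 for meningeal markers and 0.090 for ribosomal genes without WT replicate 2, 0.068 for ribosomal genes without KO replicate 2 and -0.17 for oligodendrocyte markers without WT replicate 3. Without KO replicate 2 of the vehicle group 16 lists passed, and without the 4 libraries rich in Ttr, an alternative chosen after seeing the data that leaves 1 KO library in each treatment, 43 genes and 14 lists did.

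The same question after FG7142 again gave Kpna1 as the 1 gene past the threshold (-6.10 ± 0.14, adjusted p = 1.3e-09, edgeR). 1700024P16Rik was again second by p, at -1.21 ± 0.18 (adjusted p = 0.239, both KO libraries below the 3 WT libraries). The scavenger receptor gene Stab1 (-0.75 ± 0.13) and Plxnb3 (-0.93 ± 0.17) were lower in KO and the neural stem cell factor Sox2 (0.63 ± 0.11) higher, each with an adjusted p = 0.307. Sphk1 was lower in KO here, at -0.72 ± 0.42 (adjusted p = 0.460), and Mecp2 differed by 0.080 ± 0.088 (adjusted p = 0.691). In edgeR 2292 genes had an unadjusted p under 0.05, and 1063, 1408 or 931 without WT FG7142 replicate 2, WT FG7142 replicate 3 or KO FG7142 replicate 1. Without the libraries rich in Ttr there were 1401, against 1484 under vehicle.

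With the preset correlation 15 of the 34 lists passed between KO and WT after FG7142, 9 higher and 6 lower, and with an estimated one 0 did, the lowest adjusted p being 0.578. The glucocorticoid response list was lower in KO (25 of 27 members below 0, median -0.33, adjusted p = 3.9e-06, and adjusted p = 0.578 with an estimated correlation). The sulfotransferase gene Sult1a1 was at -0.55 ± 0.10, the 1 member past the threshold over the list alone, and the arrestin-domain gene Arrdc2 at -0.96 ± 0.27. Oligodendrocyte markers were lower (23 of 24 members below 0, median -0.43, adjusted p = 3.9e-06, and adjusted p = 0.578 with an estimated correlation). The myelin regulator Myrf was at -0.53 ± 0.12 and Hapln2 at -0.60 ± 0.13, which were the 2 members that passed adjusted over the list alone. Heat shock and chaperone genes were higher (18 of 20 members above 0, median 0.21, adjusted p = 3.9e-06, and adjusted p = 0.578 with an estimated correlation), led by Hspa1a at 0.99 ± 0.22 and Hspa1b at 1.03 ± 0.29, near-identical copies whose reads the counting can share, and both passed over the list alone. Over all genes tested 0 members of these lists passed. Ribosomal protein genes were higher (77 of 77 members above 0, median 0.18, adjusted p = 4.4e-16, and adjusted p = 0.578 with an estimated correlation) with Rps10 at 0.51 ± 0.14, and so were nuclear-encoded genes of the respiratory chain (70 of 74 members above 0, median 0.089, adjusted p = 2.1e-05, and adjusted p = 0.659 with an estimated correlation). Meningeal markers lay below WT in this pair of groups (26 of 29 members below 0, median -0.59, adjusted p = 2.7e-04, and adjusted p = 0.587 with an estimated correlation). Ogn was at -0.85 ± 0.29. Choroid plexus markers lay above WT (27 of 29 members above 0, median 1.32, adjusted p = 0.0080, and adjusted p = 0.684 with an estimated correlation), with scores of 1.32 and -1.57 in the 2 KO libraries. Their median was -0.73 without KO FG7142 replicate 1, 2.10 without KO FG7142 replicate 2 and -0.71 without the libraries rich in Ttr, so the direction rested on KO FG7142 replicate 1. Astrocyte (median -0.12), endothelial and pericyte (median -0.15) and oligodendrocyte precursor markers (median -0.24) were lower, with Ntsr2 at -0.48 ± 0.11 (the 1 astrocyte marker past the threshold over the list alone), Vtn at -0.39 ± 0.12 and Vcan at -0.44 ± 0.12, at adjusted p = 0.578, 0.578 and 0.578 with an estimated correlation. Striatal (median 0.53), nuclear transport (median 0.10), anxiety-related peptide and monoamine (median 0.16), neocortical (median 0.21) and interneuron lists (median 0.14) were higher, with the adrenergic receptor gene Adrb1 at 0.47 ± 0.13 and Rangap1 at 0.24 ± 0.087, and each had an adjusted p = 0.578 with an estimated correlation. DESeq2 called 119 genes and limma-voom 1. With each library left out in turn, 4 of the 15 lists (glucocorticoid response, heat shock, ribosomal and respiratory chain) passed in the same direction. Of the other 11, all but the choroid plexus list did not pass without KO FG7142 replicate 2. Interneuron markers also did not pass without WT FG7142 replicate 1 or 2, nuclear transport genes without 2, neocortical markers without 3, and oligodendrocyte precursor markers without 2 or 3. The median of oligodendrocyte markers was -0.18 without KO FG7142 replicate 2, -0.20 without WT FG7142 replicate 2 and -0.75 without KO FG7142 replicate 1, where it was 0.23 for striatal, -0.20 for astrocyte and 0.058 for respiratory chain lists. Heat shock genes had 0.13 without KO FG7142 replicate 2. This comparison rests on 2 KO libraries, and without KO replicate 2 of the FG7142 group 6 lists passed. Without the libraries rich in Ttr, 6 genes and 23 lists passed.

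Averaged over both treatments, 2 genes were past the threshold between KO and WT. Kpna1 was the first and 1700024P16Rik the other (-1.21 ± 0.12, adjusted p = 0.00443, edgeR), at 5.80 ± 0.770 and 4.98 ± 0.530 CPM in the WT groups (SD, n = 3 each) against 2.50 ± 0.302 CPM (SD, n = 3) and 2.16 ± 0.106 CPM (SD, n = 2) in KO. All 5 KO libraries were below all 6 WT libraries, with 128 to 198 reads against 297 to 435. The locus spans 104835301 to 105016864 of chromosome 4. The next genes by p did not pass, with the collagen gene Col22a1 at -0.77 ± 0.13, Plxnb3 at -0.67 ± 0.11 and the histone gene H2afx at 0.57 ± 0.10 (adjusted p = 0.322, 0.322 and 0.340). Sphk1 differed by 0.20 ± 0.28 and Mecp2 by -0.012 ± 0.059. For Sphk1 the value was 0.48, 0.098 and 0.070 without WT vehicle replicate 1, 2 or 3 and 0.061 and 0.31 without WT FG7142 replicate 1 or 3. Leaving out KO replicate 1 or 2 of the FG7142 group left 1700024P16Rik short of the threshold, at adjusted p = 0.0911 and 0.0655, with log2 fold changes of -1.19 and -1.24, and its adjusted p ran from 5.6e-17 to 0.0911 over the alternatives. Without WT vehicle replicate 3 or FG7142 replicate 1, H2afx or Plxnb3 passed as well, and without the libraries rich in Ttr 204 genes did.

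Lists gave 10 calls for this average with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.624). Oligodendrocyte markers were lower in KO (23 of 24 members below 0, median -0.37, adjusted p = 8.9e-11, and adjusted p = 0.624 with an estimated correlation). Myrf was at -0.39 ± 0.081 and Hapln2 at -0.32 ± 0.088, and 3 of them passed adjusted over the list alone. Precursor markers were lower too (12 of 14 members below 0, median -0.15, adjusted p = 7.3e-04, and adjusted p = 0.624 with an estimated correlation). Vcan was at -0.36 ± 0.083 and the sialidase gene Neu4 at -0.44 ± 0.12, 2 that passed over the list alone. Heat shock genes were higher (19 of 20 members above 0, median 0.12, adjusted p = 1.3e-04, and adjusted p = 0.624 with an estimated correlation). Hspa1a was at 0.70 ± 0.15 and Hspa1b at 0.83 ± 0.19, which passed over the list alone. Delayed activity-regulated genes were higher (19 of 25 members above 0, median 0.15, adjusted p = 0.016, and adjusted p = 0.624 with an estimated correlation). Kcnj4 was at 0.32 ± 0.065 and Vgf at 0.50 ± 0.11, both past the threshold over the list alone. Ribosomal protein genes (76 of 77 members above 0, median 0.16, adjusted p = 8.4e-26, and adjusted p = 0.624 with an estimated correlation) were higher, with Rps10 at 0.43 ± 0.092, which passed over the list alone, and Rpl27a at 0.34 ± 0.085. Also higher were choroid plexus (median 1.23), striatal (median 0.34, Ppp1r1b 0.49 ± 0.15) and respiratory chain lists (median 0.058), at adjusted p = 0.724, 0.624 and 0.738 with an estimated correlation. The respiratory chain median lay at the 81.0 percentile of random lists matched for transcript length, whose median was 0.039. Astrocyte (median -0.082, Aqp4 -0.24 ± 0.065) and glucocorticoid response lists (median -0.13, Arrdc3 -0.26 ± 0.078) were lower, both at adjusted p = 0.624 with an estimated correlation. Over all genes tested 0 members of these lists passed. Whichever single library was left out, 6 of the 10 lists passed in the same direction, and the exceptions were the choroid plexus (median 0.018 without KO FG7142 replicate 1), astrocyte, delayed activity-regulated and glucocorticoid response lists, the last 3 without KO FG7142 replicate 2, and also without KO vehicle replicate 1, WT vehicle replicate 1 and WT vehicle replicate 2 in that order. Medians were 2.58 for choroid plexus markers without WT vehicle replicate 1, -0.56 for oligodendrocyte markers without KO FG7142 replicate 1, 0.061 for heat shock genes without KO FG7142 replicate 2, and 0.13 for striatal and 0.036 for respiratory chain lists without KO vehicle replicate 2. Without the libraries rich in Ttr 20 lists passed. DESeq2 called 122 genes, limma-voom 2, and 2062 had an unadjusted p under 0.05 in edgeR (1062 without KO FG7142 replicate 1 and 1345 without WT vehicle replicate 2).

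In WT animals the question was what FG7142 did within 30 min. Transcripts of the glucocorticoid response list were higher after the drug, 22 of 27 above 0 with a median log2 fold change of 0.43. Sult1a1 went from 10.3 ± 0.871 to 16.9 ± 0.505 CPM (SD, n = 3 each), a log2 fold change of 0.72 ± 0.089 (adjusted p = 0.0956, edgeR). The metallothionein gene Mt2 (0.90 ± 0.15), the connexin gene Gjb6 (0.63 ± 0.13) and Tsc22d3 (0.70 ± 0.18), which encodes the glucocorticoid-induced leucine zipper, lay in the same direction. The list passed camera with the preset correlation (adjusted p = 6.7e-27) and with an estimated one (adjusted p = 0.0355), the 1 of 84 list calls over 7 comparisons that did both, while fry gave adjusted p = 0.105. Adjusted over the list alone 13 members rose, against 0 over all genes. No gene passed over all 16553 in edgeR or limma-voom, while DESeq2 called 15. In edgeR 550 had an unadjusted p under 0.05 (836 without WT FG7142 replicate 1). At 3.32% of genes tested, the 550 were below the share of 0.05 that unchanged genes would give. Without WT vehicle replicate 2, whose list score of 0.144 was above those of the other 2 vehicle-treated WT libraries (-0.279 and -0.299), the median was 0.56 and 1 gene passed, Hif3a, a member of the list named here after its value was seen. Outside the list, the heparan sulfate proteoglycan gene Sdc4 (0.51 ± 0.079, adjusted p = 0.365), Cyp2d22 (0.37 ± 0.073) and A4galt (0.79 ± 0.16) were among the 5 smallest p.

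**Figure D3:**
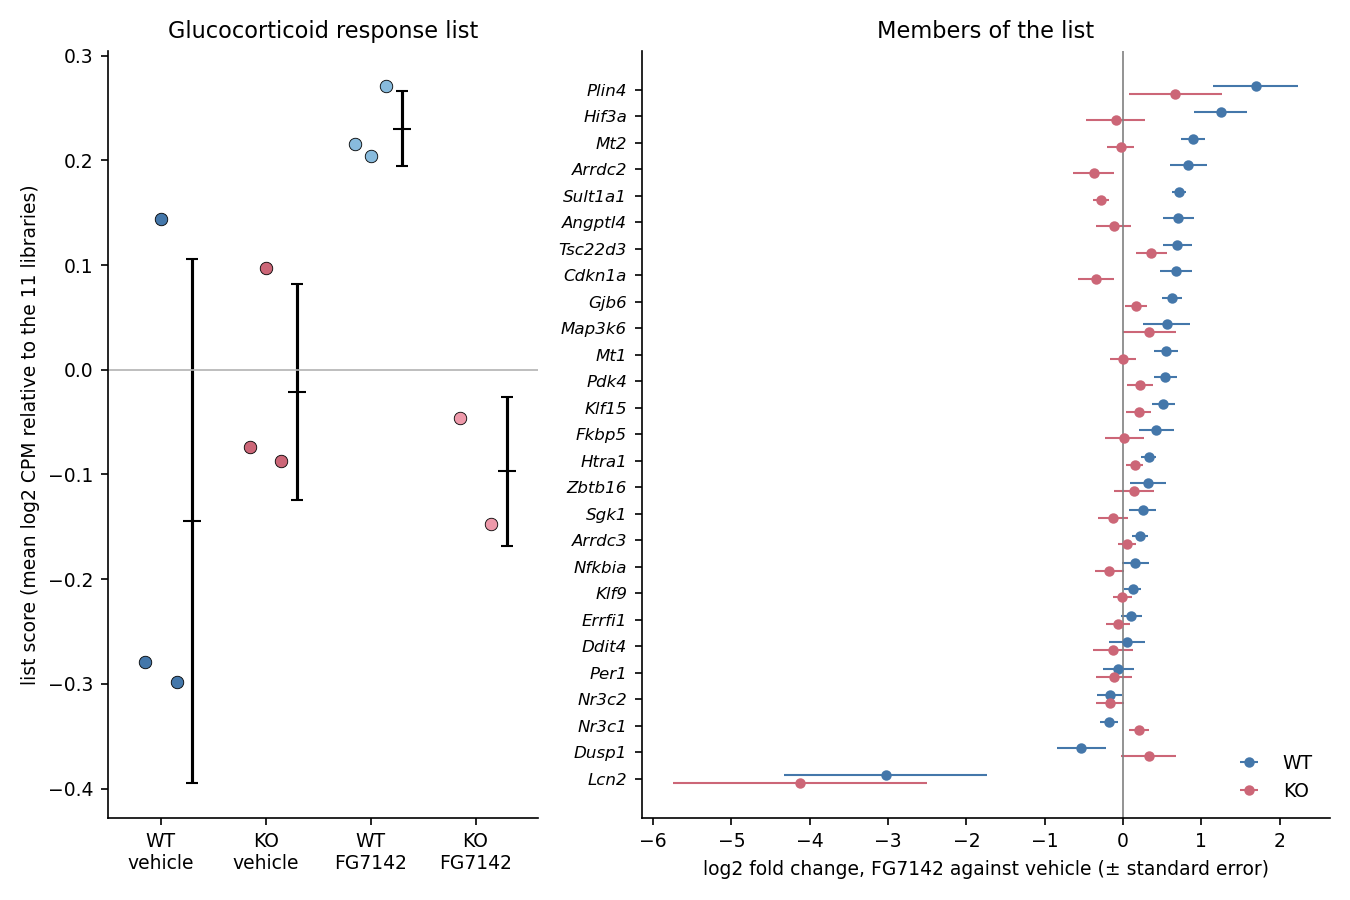
Score of the glucocorticoid response list in each library by group (left; mean log2 CPM of 27 members relative to the mean of the 11 libraries; points are libraries, the bar is the mean ± SD with n = 3, 3, 3 and 2) and log2 fold change of each member after FG7142 with its standard error in WT and KO (right). The 3 FG7142-treated WT libraries scored 0.204 to 0.271 and the other 8 libraries -0.299 to 0.144.

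Immediate early genes, the transcription factors and signalling genes that neuronal activity induces within minutes, were not higher after FG7142 in WT. As a list they were lower (31 of 40 members below 0, median -0.15, adjusted p = 3.1e-05, and adjusted p = 0.464 with an estimated correlation). Fos was at -1.06 ± 0.47, Arc at -0.78 ± 0.24, Npas4 at -0.86 ± 0.40, Junb at -0.68 ± 0.23 and Ier2 at -0.66 ± 0.19. Values for Egr1, Egr2 and Nr4a1 were -0.36 ± 0.28, -1.06 ± 0.53 and -0.46 ± 0.25, those for Dusp1 and Btg2 -0.53 ± 0.31 and -0.34 ± 0.20, and that for Fosb -0.065 ± 0.23, and no gene of the list passed adjusted over the list alone. WT vehicle replicate 1 carried much of this, and without it the list passed at a median of -0.088, with Fos at -0.48, Egr2 at -0.54, Ier2 at -0.41, Nr4a1 at -0.18, Egr1 at -0.15, Dusp1 at -0.10, Btg2 at -0.0061 and Fosb at 0.061. Among the 9 lists that passed with the preset correlation, astrocyte markers were higher (18 of 20 members above 0, median 0.14, adjusted p = 4.4e-07, and adjusted p = 0.464 with an estimated correlation). Aldh1l1 was at 0.31 ± 0.11, and Gjb6, the 1 past the threshold over the list alone, is also in the glucocorticoid list. Microglia markers were higher (20 of 22 members above 0, median 0.16, adjusted p = 6.1e-08, and adjusted p = 0.719 with an estimated correlation). The complement gene C1qa was at 0.35 ± 0.10 and Itgam at 0.29 ± 0.088. Ribosomal (74 of 77 members above 0, median 0.13, adjusted p = 1.3e-18, and adjusted p = 0.719 with an estimated correlation) and respiratory chain genes (68 of 74 members above 0, median 0.066, adjusted p = 1.2e-06, and adjusted p = 0.852 with an estimated correlation) were slightly higher. Glutamate receptor genes were lower (20 of 27 members below 0, median -0.065, adjusted p = 0.036, and adjusted p = 0.387 with an estimated correlation), close to the median of -0.067 of the longest 10% of transcripts in this comparison, and they did not pass without WT vehicle replicate 1 or 2 or WT FG7142 replicate 1 or 3. Grin2b was at -0.66 ± 0.23. Choroid plexus markers were lower (28 of 29 members below 0, median -1.68, adjusted p = 8.5e-06, and adjusted p = 0.852 with an estimated correlation), Tmem72 at -4.49 ± 2.05, and their median was 0.27 without the 1 vehicle-treated WT library rich in Ttr. Meningeal markers were higher (25 of 29 members above 0, median 0.30, adjusted p = 1.5e-05, and adjusted p = 0.852 with an estimated correlation), Gjb2 at 0.36 ± 0.15. Sphk1 was at 0.61 ± 0.37 and Mecp2 at -0.053 ± 0.079, neither past the threshold. For Sphk1 the value was 1.19 without WT vehicle replicate 1, 0.36 without WT vehicle replicate 3 and 0.38 without WT FG7142 replicate 3. With 1 library left out in turn, 5 of the 9 lists (glucocorticoid response, immediate early, astrocyte, microglia and ribosomal) passed in the same direction, while respiratory chain genes did not pass without WT vehicle replicate 1 or 2, nor meningeal markers (median 0.085) without WT vehicle replicate 2. Medians were 0.56 for meningeal markers without WT vehicle replicate 1, 0.15 for respiratory chain and 0.21 for ribosomal genes without WT vehicle replicate 3, 0.086 for ribosomal genes without WT vehicle replicate 2 and 0.098 for microglia markers without WT FG7142 replicate 1. Without WT replicate 2 of the FG7142 group 14 lists passed.

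**Figure D4:**
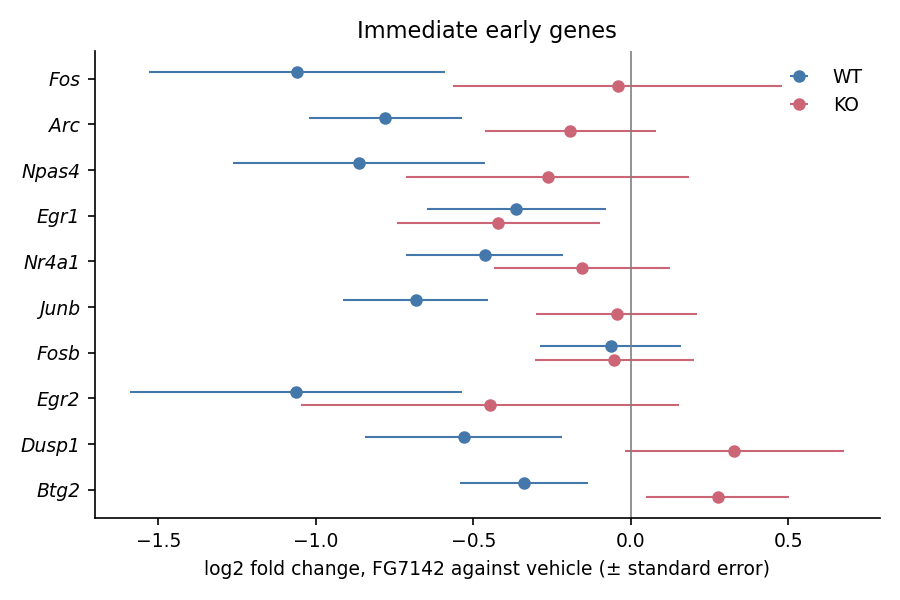
Log2 fold change after FG7142 against vehicle of the 10 immediate early genes named before the data were examined, in WT and KO, with bars for the standard error. In WT the values ran from -1.06 for Fos and Egr2 to -0.065 for Fosb, and in KO from -0.45 for Egr2 to 0.33 for Dusp1.

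The same drug comparison was made in KO animals. The smallest p belonged to the lactate receptor gene Gpr81, lower after FG7142 at -1.23 ± 0.23 (adjusted p = 0.429, edgeR), followed by Stab1 (-0.67 ± 0.13), the pericyte-associated gene Vtn (-0.60 ± 0.12), the centrosomal gene Ninl (-0.74 ± 0.15) and Atp2a1 (-2.70 ± 0.55). Sphk1 was lower after the drug, from 2.04 ± 0.253 CPM (SD, n = 3) to 0.878 ± 0.0329 CPM (SD, n = 2), a log2 fold change of -1.22 ± 0.43 (adjusted p = 0.429, edgeR), and Mecp2 was at 0.13 ± 0.088. Of the immediate early genes, Arc (-0.19 ± 0.27), Egr1 (-0.42 ± 0.32), Egr2 (-0.45 ± 0.60), Npas4 (-0.26 ± 0.45), Nr4a1 (-0.16 ± 0.28), Fos (-0.043 ± 0.52), Junb (-0.046 ± 0.26) and Fosb (-0.053 ± 0.25) had values below 0 and Dusp1 (0.33 ± 0.35) and Btg2 (0.27 ± 0.23) above it, and none passed. The glucocorticoid response list had a median of -0.011 (12 members above 0 and 15 below, with the test toward higher values, adjusted p = 0.80). No gene passed in edgeR or limma-voom, 1896 had an unadjusted p under 0.05 in edgeR (952 without KO FG7142 replicate 1, 1266 without KO FG7142 replicate 2 and 462 with the meningeal score as a covariate, chosen after seeing the data), and DESeq2 called 21.

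Meningeal markers were lower in KO animals after FG7142 (28 of 29 members below 0, median -1.05, adjusted p = 3.2e-15, and adjusted p = 0.527 with an estimated correlation). Gjb2 was at -0.70 ± 0.17, Slc6a20a at -1.05 ± 0.26 and Thbd at -0.65 ± 0.16, and 6 passed adjusted over the list alone against 0 over all genes. Choroid plexus (29 of 29 members below 0, median -1.36, adjusted p = 0.0011, and adjusted p = 0.762 with an estimated correlation) and ependymal markers (18 of 19 members below 0, median -0.57, adjusted p = 0.023, and adjusted p = 0.762 with an estimated correlation) were lower as well. Neither passed without KO vehicle replicate 3 (medians -0.39 and -0.080) or KO FG7142 replicate 2 (-0.50 and -0.082), and without KO FG7142 replicate 1 the medians were -3.38 and -1.23. Endothelial and pericyte markers were lower (15 of 25 members below 0, median -0.11, adjusted p = 0.0060, and adjusted p = 0.743 with an estimated correlation). Pdgfrb was at -0.48 ± 0.13 and Vtn among 3 that passed over the list alone. Microglia markers were higher (19 of 22 members above 0, median 0.22, adjusted p = 6.6e-05, and adjusted p = 0.762 with an estimated correlation). Siglech was at 0.34 ± 0.12 and Gpr34 at 0.42 ± 0.15. Interneuron (23 of 25 members above 0, median 0.15, adjusted p = 2.7e-04, and adjusted p = 0.418 with an estimated correlation) and GABAergic genes (23 of 27 members above 0, median 0.10, adjusted p = 0.0063, and adjusted p = 0.418 with an estimated correlation) were higher, with the receptor subunit gene Gabrg1 at 0.62 ± 0.21. Heat shock genes were higher (15 of 20 members above 0, median 0.14, adjusted p = 0.0034, and adjusted p = 0.762 with an estimated correlation). Dnajb1 was at 0.51 ± 0.14 and Sdf2l1 at 0.82 ± 0.24. Higher values were also found for ribosomal (median 0.17), respiratory chain (median 0.13), peptide and monoamine (median 0.16, Oprl1 0.28 ± 0.085), neocortical (median 0.12), nuclear transport (median 0.064) and clock lists (median 0.067, Nr1d1 0.45 ± 0.13), and lower values for interferon-stimulated genes (median -0.23, Ddx58 -0.32 ± 0.13). With an estimated correlation these 7 lists had adjusted p from 0.418 to 0.762. In all, 15 lists passed with the preset correlation, 10 higher and 5 lower, and 0 with an estimated one. Whichever single library was left out, 6 of the 15 (meningeal, interneuron, GABAergic, ribosomal, respiratory chain and peptide and monoamine) passed in the same direction. Without KO FG7142 replicate 2 the endothelial, heat shock (median -9.9e-04), interferon, neocortical (median 0.0093), nuclear transport and clock lists did not pass, and each of them also did not pass without at least 1 of the vehicle-treated KO libraries. Microglia markers did not pass without KO vehicle replicate 1 or KO FG7142 replicate 1. Without KO replicate 2 of the FG7142 group 8 lists passed.

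Averaged over genotypes, FG7142 was compared with vehicle in all 11 libraries. The smallest p were those of Sdc4 (0.37 ± 0.059), Erbb3 (-0.50 ± 0.086), Ninl (-0.55 ± 0.10), the endoplasmic reticulum stress gene Herpud1 (0.47 ± 0.085) and the cold-shock gene Rbm3 (0.64 ± 0.12), each at adjusted p = 0.530 in edgeR. Glucocorticoid response genes were higher on average (21 of 27 members above 0, median 0.22, adjusted p = 1.2e-08, and adjusted p = 0.546 with an estimated correlation), 8 higher and 1 lower over the list alone, with Gjb6 at 0.40 ± 0.10 and Tsc22d3 at 0.53 ± 0.13. Microglia markers were higher (21 of 22 members above 0, median 0.18, adjusted p = 6.5e-10, and adjusted p = 0.546 with an estimated correlation). Itgam, at 0.28 ± 0.065, passed over the list alone, and Tmem119 was at 0.31 ± 0.090. Immediate early genes were lower (30 of 40 members below 0, median -0.12, adjusted p = 0.0051, and adjusted p = 0.546 with an estimated correlation). Dusp5 was at -0.32 ± 0.095 and Arc at -0.49 ± 0.18. Vascular markers were lower (17 of 25 members below 0, median -0.081, adjusted p = 0.028, and adjusted p = 0.587 with an estimated correlation). The VEGF receptor gene Kdr was at -0.42 ± 0.10 and Pdgfrb at -0.37 ± 0.087, and 1 marker passed higher and 3 lower over the list alone. Ribosomal (median 0.14, Rps4x 0.22 ± 0.061), respiratory chain (median 0.10, Ndufb9 0.22 ± 0.063), astrocyte (median 0.091, of which Gjb6 passed over the list alone), peptide and monoamine (median 0.067), clock (median 0.026, Nr1d1 0.28 ± 0.090) and interneuron lists (median 0.058) were higher. Choroid plexus (median -1.44), meningeal (median -0.38, Thbd -0.31 ± 0.11), ependymal (median -0.42) and oligodendrocyte lists (median -0.11, led by Enpp2, which the choroid plexus list also holds) were lower. Choroid plexus markers did not pass without KO FG7142 replicate 2 (median -1.04), and had -0.51 without WT vehicle replicate 1 and -2.39 without KO FG7142 replicate 1. Ependymal markers did not pass without WT vehicle replicate 3 (-0.30), KO vehicle replicate 3 (-0.16) or KO FG7142 replicate 2 (-0.24), and had -0.80 without KO FG7142 replicate 1. Meningeal markers did not pass without WT vehicle replicate 1 (-0.097). Oligodendrocyte, clock, interneuron and vascular lists did not pass without KO FG7142 replicate 2, where the oligodendrocyte median was 0.014, nor without 1 or more other libraries. All 14 passed with the preset correlation and 0 with an estimated one, where adjusted p ran from 0.546 to 0.789. Of the other immediate early genes, Egr2 was at -0.76 ± 0.40, Npas4 at -0.56 ± 0.30, Fos at -0.55 ± 0.35, Egr1 at -0.39 ± 0.21, Junb at -0.36 ± 0.17, Nr4a1 at -0.31 ± 0.19, Dusp1 at -0.10 ± 0.23, Fosb at -0.059 ± 0.17 and Btg2 at -0.032 ± 0.15. Sphk1 was at -0.30 ± 0.28 (-0.015 without WT vehicle replicate 1 and -0.17 without WT FG7142 replicate 1), Mecp2 at 0.039 ± 0.059 and Kpna1 at -0.073 ± 0.077. No gene passed in edgeR or limma-voom, 1461 had an unadjusted p under 0.05 in edgeR (2328 without KO vehicle replicate 2 and 960 without WT FG7142 replicate 1), and DESeq2 called 16. Without WT vehicle replicate 1 Fos was at -0.26, Egr2 at -0.49, Dusp1 at 0.11 and Btg2 at 0.13, and without KO vehicle replicate 2 the immediate early list did not pass (median -0.058) and Fos was at -0.27. With any 1 library left out, 6 of the 14 lists (glucocorticoid response, microglia, ribosomal, respiratory chain, astrocyte and peptide and monoamine) passed in the same direction. Without KO replicate 2 of the FG7142 group 9 lists passed.

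The interaction asked whether the response to FG7142 differed between genotypes. Sult1a1 had the smallest p, with a response lower in KO than in WT by a log2 difference of -1.0 ± 0.13 (adjusted p = 0.207, edgeR). Gpr81 (-1.90 ± 0.30), the macrophage genes Stab1 (-0.90 ± 0.17) and Cd163 (-1.49 ± 0.30) and the meningeal gene Gjb2 (-1.06 ± 0.22) followed, all lower. Part of each difference lay in the vehicle groups. There Sult1a1 had 916 to 1067 reads in KO against 636 to 725 in WT, and Gpr81 106 to 141 against 62 to 74. Under vehicle Stab1 had 1389 to 1615 against 1131 to 1364, Cd163 147 to 159 against 86 to 100 and Gjb2 531 to 608 against 235 to 348. The difference for Sphk1 was -1.82 ± 0.56 (adjusted p = 0.779), for Mecp2 0.18 ± 0.12 and for Kpna1 0.085 ± 0.15. Of the immediate early genes, Fos differed by 1.02 ± 0.70, Dusp1 by 0.86 ± 0.47, Junb by 0.64 ± 0.34, Btg2 by 0.61 ± 0.30 and Arc by 0.59 ± 0.36, with Egr2 at 0.62 ± 0.79, Npas4 at 0.60 ± 0.60, Nr4a1 at 0.31 ± 0.37, Fosb at 0.012 ± 0.34 and Egr1 at -0.057 ± 0.43, and none passed. Without WT vehicle replicate 1 Fos was at 0.44, Dusp1 at 0.43, Btg2 at 0.28, Nr4a1 at 0.027 and Egr2 at 0.092. The glucocorticoid response list differed by a median of -0.33 (24 of 27 members below 0, adjusted p = 8.0e-08, and adjusted p = 0.246 with an estimated correlation), with Mt2 at -0.93 ± 0.23. Meningeal markers differed by more (29 of 29 members below 0, median -1.19, adjusted p = 2.2e-22, and adjusted p = 0.246 with an estimated correlation). Slc6a20a was at -1.19 ± 0.34. Interneuron markers differed in the other direction (22 of 25 members above 0, median 0.24, adjusted p = 1.7e-04, and adjusted p = 0.246 with an estimated correlation). Dlx5 was at 0.51 ± 0.21. Adjusted over the list alone, 9 meningeal, 2 glucocorticoid and 1 of the endothelial and pericyte markers (Vtn, -0.67 ± 0.15) passed, all lower. With the preset correlation 12 of the 34 lists passed, 8 higher and 4 lower, and 0 with an estimated one. Whichever single library was left out, 6 of the 12 (meningeal, glucocorticoid response, interneuron, peptide and monoamine, heat shock and GABAergic) passed in the same direction. The glucocorticoid median was -0.20 without KO vehicle replicate 2 and that of the peptide and monoamine list 0.12 without WT vehicle replicate 1. Ribosomal genes were on the other side of 0 without WT vehicle replicate 3 (median -0.027) or KO vehicle replicate 1 (-0.019) and did not pass without KO vehicle replicate 3, WT FG7142 replicate 2 or 3 or either KO FG7142 library. The respiratory chain list was on the other side of 0 without WT vehicle replicate 3 (-0.019) and did not pass without KO vehicle replicate 1, WT FG7142 replicate 3 or KO FG7142 replicate 1. Interferon-stimulated genes did not pass without WT FG7142 replicate 3, nuclear transport genes without WT vehicle replicate 2, endothelial markers without WT vehicle, KO vehicle or KO FG7142 replicate 2, and neocortical markers without WT vehicle replicate 1, KO vehicle replicate 1 or 3 or KO FG7142 replicate 2. No gene passed in edgeR or limma-voom, 994 had an unadjusted p under 0.05 in edgeR (2015, 455 and 538 without WT FG7142 replicate 1, 2 or 3, 604 without KO FG7142 replicate 1 and 616 without WT vehicle replicate 3), and DESeq2 called 7. In data simulated for this comparison the test recovered 17.9% of 1.5-fold, 59.7% of 2-fold and 87.9% of 4-fold differences. With 200 genes changed at once, these shares can overstate the real power.

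Across the 16552 genes other than Kpna1, the fold changes of KO against WT under vehicle and after FG7142, which share no library, had a Pearson correlation of 0.20 and a Spearman correlation of 0.22, with 57.8% of genes of the same sign. For FG7142 in WT and in KO the values were 0.20, 0.13 and 54.4%. These are correlations across genes, which are not independent replicates, and no test was made. The agreement of the genotype effect between independent libraries was 0.0074 without KO FG7142 replicate 1, 0.091 without WT vehicle replicate 2 and 0.0999 without KO vehicle replicate 2. The agreement of the FG7142 effect between independent libraries was 0.012 and 0.016 without WT vehicle replicate 1 or WT FG7142 replicate 1, 0.078 without KO vehicle replicate 3, 0.34 without WT FG7142 replicate 2, and 0.31 and 0.039 without KO FG7142 replicate 1 or 2. With no filter on low counts both were lower, at 0.055 and 0.043.

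Lists for the principal cells of the hippocampus, for sphingolipids and for DNA methylation did not pass in any of the 7 comparisons. Markers of dentate granule cells (20 genes) had medians between -0.18 and 0.11, CA1 pyramidal cells (15) between -0.011 and 0.13, and CA3 and CA2 pyramidal cells (19) between -0.068 and 0.046. Genes of sphingolipid metabolism and its receptors (38) lay between -0.048 and 0.014, readers and writers of DNA methylation (25) between -0.065 and 0.015, and genes reported to respond to MeCP2 (31) between -0.043 and 0.11. Thalamic and habenular (25, -0.045 to 0.21), blood cell (8, -0.35 to 0.11) and sex-linked lists (6, -0.42 to -0.022), 51 listed chromosomal neighbours of Kpna1 (-0.041 to 0.045) and 137 genes within 10 Mb of it (-0.026 to 0.015) did not pass either. The lowest adjusted p among these 11 lists was 0.067 with the preset correlation. Adjusted over the list alone, 3 chromosomal neighbours and 1 dentate marker were lower in KO over both treatments and 1 CA1 marker lower after FG7142 over both genotypes, against 0 over all genes. In comparisons where their own list did not pass, 1 astrocyte marker was lower and 1 glucocorticoid response gene higher in KO under vehicle, 1 delayed activity-regulated gene higher in KO after FG7142 and 2 immediate early genes higher in KO over both treatments by the same adjustment. Median, mean and test disagreed in sign in 37 of 238 list tests, and 0 of those passed. Of 26 mitochondrially encoded transcripts listed, 0 were in the table.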

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

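For Sphk1, the glucocorticoid response list and 1700024P16Rik, the tests by correlation, covariate, neighbouring gene and genomic window, the use of the interaction to weigh explanations and the count of list members over splits were chosen only after the results were seen, while the comparisons, the list tests and the other 8 counts over splits were set beforehand.

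The response to FG7142 differed between KO and WT in 12 gene lists by the test of the interaction with camera's preset correlation, and in 0 of them with an estimated correlation. As the median difference between the log2 response in KO and that in WT, meningeal and fibroblast markers had -1.19, the glucocorticoid response list -0.33, interferon-stimulated genes -0.28 and endothelial and pericyte markers -0.11. The difference was 0.24 for interneuron markers, 0.23 for neuropeptide and monoamine signalling, 0.22 for heat shock and chaperones, 0.16 for GABA receptors and GABAergic signalling and 0.16 for neocortical markers. Nuclear transport receptors had a difference of 0.095, the nuclear-encoded respiratory chain 0.054 and cytosolic ribosomal proteins 0.045. With an estimated correlation their adjusted p ran from 0.246 to 0.929.

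Sphk1 was higher in KO than WT under vehicle (log2 fold change 1.11 ± 0.37, and 1.69 without WT vehicle replicate 1) and lower under FG7142 (-0.72 ± 0.42), without passing. Meningeal tissue in the dissected samples is a candidate source, since deviations of Sphk1 from the group means had a positive correlation with the meningeal score over the 11 libraries, which did not pass (two-sided, r = 0.865, exact permutation p = 0.0995, BH-adjusted p = 0.199 over 2 relations; rho = 0.864, exact permutation p = 0.0532, BH-adjusted p = 0.106; r = 0.803 without the 2 farthest libraries). The libraries fell into 2 clusters by this score, so no pooled correlation is given. Deviations followed the choroid plexus score less closely (r = 0.504, exact permutation p = 0.243, adjusted p = 0.243; rho = 0.418, exact permutation p = 0.248, adjusted p = 0.248; r = 0.368 without the 2 farthest). With the meningeal score as a covariate the difference was 0.42 ± 0.29 under vehicle and -0.18 under FG7142, and the interaction -0.60 against -1.82 without it, so tissue content and an effect of importin α5 loss on Sphk1 cannot be told apart with 2 or 3 libraries per group.

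The glucocorticoid response list was higher after FG7142 in WT, with a median of 0.43, and its median in KO was -0.011. A higher share of astrocytes alone was set to lower the median to near 0 with the astrocyte score, without genes shared by both lists, as a covariate. It stayed at 0.34 (adjusted p = 1.3e-19, camera with the preset correlation). The full astrocyte score varied little within the WT groups (SD 0.017 under vehicle and 0.035 after FG7142) and most in KO under vehicle (SD 0.13). The adjustment thus rests largely on other groups than those compared and cannot exclude a share of astrocytes. With both tissue scores as covariates it was 0.42 (adjusted p = 4.1e-19, camera), which argues against meninges and choroid plexus as the whole cause. A response that needs importin α5 may exist, but the interaction of the list had an adjusted p = 0.246 with an estimated correlation, and this stays open. In 10 splits of the 6 WT libraries the real one gave 13 members past the threshold over the list alone and the highest other 1, and 10 splits are too few for a share under 0.05.

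1700024P16Rik was lower in KO than WT over both treatments, with a log2 fold change of -1.21 ± 0.12. With both tissue scores as covariates it was -1.21 (adjusted p = 0.0113, edgeR), which argues against choroid plexus and meninges as the whole cause. In that fit it was -0.96 under vehicle and -1.45 under FG7142, neither of which passed. Without either of the KO FG7142 libraries the difference over both treatments did not pass, as given above. Content of other tissue, such as that marked by the oligodendrocyte or striatal lists, was not used as a covariate and stays open. Reads of adjacent genes counted as this gene would lower those genes too. The 3 tested genes within 0.2 Mb had log2 fold changes of 0.062 ± 0.077 (Dab1), 0.022 ± 0.079 (Ppap2b) and -0.040 ± 0.072 (Prkaa2). Their mean log2 CPM was 7.04, 8.03 and 5.21, while 1700024P16Rik lay at a few CPM. A loss of its size is small beside their levels and spread, so these values cannot exclude such reads. A segment of another strain on chromosome 4 could lower the gene and cannot be told apart from an effect of importin α5 loss, since 17.3% of 75 genes within 5 Mb had an unadjusted p under 0.05 against 12.4% of other genes (Fisher's exact test, two-sided p = 0.217) and a variant of this gene alone would not move its neighbours. Within 10 Mb of Kpna1, looked at first, the share was 13.9% against 12.4% (Fisher's exact test, two-sided p = 0.603).

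Other splits of the same libraries were run for comparisons with at least 3 libraries per arm. For KO against WT under vehicle the real split gave 1 gene and 9 lists and the highest other split 23 genes and 21 lists, and for FG7142 in WT the real split gave 0 genes and 9 lists and the highest other 0 genes and 15 lists. With 10 splits each, no share under 0.05 can be reached. For KO against WT over both treatments, 6 of 100 splits, the real one among them, gave at least 2 genes and 67 at least 10 lists. Other splits had at most 850 genes and 19 lists. Chance can thus not be excluded for these numbers of calls. The count does not follow which genes pass, so it leaves the targeted gene Kpna1 as it was (118 to 153 reads per KO library against 8188 to 10477 per WT library). For 1700024P16Rik by itself it decides nothing. The split with 850 genes may follow a structure of the samples apart from genotype, for which no test was made. Its vehicle arms set WT replicates 1 and 2 and KO replicate 1, in which short transcripts lay lowest relative to long ones (-0.22 to -0.062 as the difference in log2 between the shortest and the longest 10%), against the other 3 (0.030 to 0.12), while its FG7142 arms overlapped in this measure. For FG7142 over both genotypes the real split gave 0 genes, which every split reaches, so the count of genes decides nothing (at most 43 in other splits). Chance cannot be excluded for its lists, as 24 of 100 splits gave at least 14 and other splits at most 22.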

How the results depend on the processing

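The covariates, the removal of libraries by their Ttr level and leaving out libraries for the correlations across genes were chosen after seeing the data, and the other alternatives were set beforehand.

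Depth limits few values here, and the number and spread of animals limit more. For named genes, 3497 values kept direction and side of the threshold, 76 crossed 0, 52 newly passed (48 with DESeq2) and 2 no longer passed. For passing lists, 1345 values were as before, 360 no longer passed and 38 crossed 0. Values kept say little where the library left out lay outside the comparison or the gene was far from passing. Some changed values are lists tested with their own score as a covariate, where the loss was fixed in advance. The cause was not tested, apart from leaving out libraries, which lowers their number.

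With RLE scaling, upper quartile scaling, the stricter filter and, for the 4 comparisons of 2 groups, fits of those groups alone, each count of genes stayed within 1.5 times its value. Of 84 list calls 37 passed in the same direction whichever single library was left out. With no filter on low counts 2 genes passed for KO against WT under vehicle, and the correlations across genes were 0.055 and 0.043. DESeq2 called 9 genes for KO against WT under vehicle, 119 under FG7142 and 122 over both treatments, 15, 21 and 16 for FG7142 in WT, in KO and over both genotypes, and 7 in the interaction. It gave no adjusted p for Sphk1, A4galt and Egr2 in the comparison of FG7142 with vehicle in WT. Camera with an estimated correlation passed 0 lists in 6 comparisons and 1 for FG7142 in WT, so 1 in all, and fry passed 0 in each of the 7 and 0 in all. With fry the glucocorticoid response list, median 0.43 in WT, had an adjusted p = 0.105. With both tissue scores as covariates 8 lists passed for FG7142 in KO and 9 for FG7142 over both genotypes, where the choroid plexus score or the meningeal score alone also gave 9. Without the libraries rich in Ttr, 43 genes and 14 lists passed for KO against WT under vehicle, 6 genes and 23 lists under FG7142, and 204 genes and 20 lists over both treatments. That fit holds 1 KO library per treatment, which is assumed to vary like the other groups. Those KO libraries had neocortical scores of 0.36 and 0.27, against -0.31 to -0.038 in the WT libraries kept. The counts of that fit therefore cannot be assigned to genotype rather than to the dissected region.

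With a block by replicate number, 3 genes passed for KO against WT over both treatments (Kpna1, Ier5l and 1700024P16Rik), and 5 list calls no longer passed. Fosb in the interaction was -0.12 with the block. Residuals of same-number libraries correlated by over 0.1 in 4 of 15 pairs, with a median of -0.019, and 3 of 11 libraries were closest to one of their own number, so the numbers were not read as paired samples.

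A list tested with its own score as a covariate has its group differences taken out, so a median near 0 was fixed in advance. This holds below for choroid plexus markers under their own or both scores and for meningeal markers under the meningeal score. With the choroid plexus score as a covariate, values on the other side of 0 for KO against WT under vehicle were -0.015 for choroid plexus markers. In KO the drug comparison had 0.079 for choroid plexus markers. Over both genotypes the drug comparison had 0.032 for choroid plexus markers and 0.078 for Btg2. With the meningeal score as a covariate, values on the other side of 0 for KO against WT under vehicle were -0.44 for choroid plexus markers and -0.014 for Calml4. Over both treatments KO against WT had 2.6e-04 for Mecp2. In KO the drug comparison had 1.28 for choroid plexus markers, 0.072 for ependymal markers, -0.0016 for heat shock and chaperones, 0.023 for meningeal and fibroblast markers, -0.011 for nuclear transport receptors, 0.44 for Fos, 0.073 for Nr4a1 and 0.13 for Egr2. Over both genotypes the drug comparison had 0.046 for Sphk1, 0.062 for Dusp1 and 0.13 for Btg2. The interaction had 0.052 for endothelial and pericyte markers, -0.0019 for nuclear transport receptors, -0.13 for Kpna1, 0.18 for Egr1 and -0.080 for Fosb. With both tissue scores as covariates, values on the other side of 0 for KO against WT under vehicle were -0.024 for choroid plexus markers and -0.033 for interferon-stimulated genes. Under FG7142 KO against WT had 0.0078 for Sphk1 and -0.013 for Mecp2. In WT the drug comparison had 0.016 for Mecp2. In KO the drug comparison had 0.040 for choroid plexus markers, -0.0036 for heat shock and chaperones, -0.044 for nuclear transport receptors, 0.76 for Fos, 0.20 for Npas4, 0.20 for Nr4a1, 0.21 for Junb, 0.015 for Fosb and 0.48 for Egr2. Over both genotypes the drug comparison had 0.025 for choroid plexus markers, 0.024 for Sphk1, 0.040 for Dusp1 and 0.13 for Btg2. The interaction had 0.050 for interferon-stimulated genes, -0.094 for nuclear transport receptors, -0.23 for Kpna1 and 0.47 for Egr1. Without the libraries rich in Ttr, values on the other side of 0 for KO against WT under vehicle were 0.089 for interneuron markers and 0.0054 for oligodendrocyte precursor markers. Under FG7142 KO against WT had -0.71 for choroid plexus markers. Over both treatments KO against WT had 0.0052 for astrocyte markers. In WT the drug comparison had 0.26 for choroid plexus markers and 0.064 for Fosb. In KO the drug comparison had -0.013 for microglia markers, -0.10 for neocortical markers, 0.0095 for Kpna1 and -8.5e-04 for Dusp1. Over both genotypes the drug comparison had -0.0039 for astrocyte markers and 0.0091 for Btg2. The interaction had -0.053 for cytosolic ribosomal proteins, -0.024 for the respiratory chain, -0.19 for neocortical markers, -0.13 for Fos, -0.33 for Npas4, -0.26 for Nr4a1, -0.47 for Fosb and -0.59 for Egr2. With limma-voom, values on the other side of 0 for FG7142 in KO were 0.15 for Fos and 0.034 for Junb. Over both genotypes the drug comparison had 0.0015 for Btg2. The interaction had 0.025 for Egr1. With upper quartile scaling, values on the other side of 0 in the interaction were -0.013 for Fosb.

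Leaving out 1 library at a time, counts of genes were 1 to 1 for KO against WT under vehicle and under FG7142, 1 to 3 over both treatments, 0 to 1 for FG7142 in WT and 0 to 0 for FG7142 in KO, over both genotypes and in the interaction. Counts of lists were 8 to 16, 6 to 19 and 10 to 14 for KO against WT under vehicle, under FG7142 and over both treatments, 9 to 14, 8 to 16 and 9 to 16 for FG7142 in WT, in KO and over both genotypes, 9 to 17 in the interaction and 66 to 99 in all. The libraries at these extremes by more than 1.5 times were KO vehicle replicate 2, KO FG7142 replicate 2 and WT FG7142 replicate 2. For genes they were WT vehicle replicate 2, without which Hif3a passed for FG7142 in WT, and KO FG7142 replicates 1 and 2, without which 1700024P16Rik did not pass. The glucocorticoid response list in WT had medians from 0.30 to 0.56. Correlations across genes were 0.0074 to 0.27 for KO against WT and 0.012 to 0.34 for FG7142.

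Some results reversed when 1 library was left out, and a group of 2 libraries then holds a lone library that is assumed to vary like the others. The ranges for KO against WT under vehicle were -0.0012 to 3.19 for choroid plexus markers. The ranges for KO against WT under FG7142 were -0.73 to 2.10 for choroid plexus markers and -1.3e-04 to 0.14 for Mecp2. The ranges for KO against WT over both treatments were -0.052 to 0.015 for Mecp2. The ranges for FG7142 in WT were -2.10 to 0.27 for choroid plexus markers, -0.20 to 0.061 for Fosb and -0.12 to 0.028 for Mecp2. The ranges for FG7142 in KO were -0.89 to 0.031 for Egr2, -0.39 to 0.52 for Fos, -0.23 to 0.26 for Fosb, -9.9e-04 to 0.20 for heat shock and chaperones, -0.31 to 0.24 for Junb, -0.065 to 0.0017 for Kpna1, -0.59 to 0.088 for Npas4 and -0.39 to 0.084 for Nr4a1. The ranges for FG7142 over both genotypes were -0.11 to 0.13 for Btg2, -0.21 to 0.11 for Dusp1, -0.15 to 0.10 for Fosb and -0.29 to 0.014 for oligodendrocyte markers. The ranges in the interaction were -0.027 to 0.13 for cytosolic ribosomal proteins, -0.31 to 0.18 for Egr1, -0.17 to 0.32 for Fosb, -0.0043 to 0.17 for Kpna1 and -0.019 to 0.10 for the respiratory chain.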

Other observations

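The tests against transcript length and matched lists and the genes singled out in this part were chosen only after the results were seen, while the tests behind the adjusted p and the list calls were set beforehand.

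Acta1 and Atp2a1, genes of muscle, had among the smallest p for KO against WT under vehicle without passing (adjusted p = 0.244 and 0.364). Acta1 was at 8.19 ± 0.754 CPM in KO and 4.67 ± 0.566 CPM in WT under vehicle (SD, n = 3 each), and Atp2a1 at 1.46 ± 1.05 and 0.223 ± 0.0591 CPM (SD, n = 3 each). After FG7142 Atp2a1 was at 0.308 ± 0.0335 CPM in WT (SD, n = 3) and 0.222 ± 0.00651 CPM in KO (SD, n = 2). No list of muscle genes had been set, so no test of such a group was made.

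Mbp and Plp1, the most abundant of the oligodendrocyte markers, had lower means in KO than WT without passing. Mbp had a mean of 2748 CPM in vehicle-treated WT and 2045 CPM in vehicle-treated KO libraries, and 2733 and 2172 CPM after FG7142. Over both treatments its log2 fold change was -0.38 ± 0.18 (adjusted p = 0.415). Plp1 had means of 1747 and 1189 CPM under vehicle and 1563 and 1146 CPM after FG7142, with -0.50 ± 0.19 over both (adjusted p = 0.362). Enpp2, the third by level and also a choroid plexus marker, went the other way, from 580 to 937 and from 180 to 411 CPM. The oligodendrocyte score ran from -0.631 to 0.513 over the 11 libraries, with both extremes in single libraries of different groups.

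Fold changes had a correlation with transcript length in several comparisons, which differed between libraries of a group. Of the genes tested 93.4% had a length in the annotation, and across those 15453 genes, which are not independent replicates, the Spearman correlation of length with the log2 fold change was -0.25 for KO against WT under vehicle and -0.21 for FG7142 in WT. It was -0.072 for KO against WT under FG7142, -0.028 for FG7142 in KO, 0.095 for the interaction, -0.18 for KO against WT over both treatments and -0.12 for FG7142 over both genotypes. By library, the shortest 10% minus the longest 10% (medians of log2 CPM relative to the 11 libraries) was -0.13, -0.22 and 0.057 in WT vehicle replicates 1, 2 and 3, -0.062, 0.12 and 0.030 in KO vehicle, -0.038, 0.093 and -0.038 in WT FG7142 and 0.13 and 0.022 in KO FG7142. WT vehicle replicates 1 and 2 were thus the 2 lowest, in the group that both comparisons with the strongest correlations share. The median of the cytosolic ribosomal proteins, which are short transcripts, lay at the 100th percentile of 10000 lists matched for length in 6 comparisons and at 97.5 in the interaction. The respiratory chain list, also of short transcripts, lay at 81.0 for KO against WT over both treatments, 95.6 under FG7142, 21.8 under vehicle, where it was not called, 96.7 for FG7142 in WT, 98.7 in the interaction and 100 for FG7142 in KO and over both genotypes. Glutamate receptor genes, with a median length of 7648 bp, were at 13.6 for FG7142 in WT, so this call did not stand out from lists of like length. The 84 list calls had been chosen by a test on the same fold changes. The matched lists hold genes drawn without regard to correlation between members. A place in their tail therefore speaks to length only and is no separate support for a call. Of the 84 list calls 72 had a median in the outer 2.5% of matched lists on the side of the call and 12 did not. Besides the 3 respiratory chain calls under 97.5 and the glutamate receptor call, these were endothelial and pericyte markers for FG7142 in KO (4.84), over both genotypes (2.68) and in the interaction (5.47), clock genes for FG7142 in KO (91.3) and over both genotypes (87.99), nuclear transport genes for FG7142 in KO (97.3) and in the interaction (96.7), and astrocyte markers for KO against WT under FG7142 (3.34). For the ribosomal list and KO against WT under vehicle the median was 0.14 and the median of the matched lists 0.043. Many ribosomal protein genes have processed pseudogenes, and how reads shared with them were counted is not known. The glucocorticoid response list, with a median length of 3553 bp, was at the 100th percentile for FG7142 in WT and at 45.8 for FG7142 in KO.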
